A study of Bombyx mori with 4 samples.

How the data were processed

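RNA was sequenced from silkworm prothoracic glands that had been held in culture medium for 1 or 3 h, with 10 nM recombinant prothoracicotropic hormone (PTTH) or without it. The 4 groups were control 1 h, PTTH 1 h, control 3 h and PTTH 3 h, each with 1 library. Per the series description, glands of 12 to 18 larvae went into each RNA preparation, and RNA of 2 preparations was pooled before sequencing. Per the labels' protocols, the members of each gland pair were separated between medium with and without the hormone, so the pooled libraries of a time point come from paired glands. Total RNA was made into paired-end mRNA libraries with an Illumina kit, per the labels' protocols.

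CASAVA 1.8.0, TopHat and SAMtools are listed in the submitters' processing notes, without a version for the latter pair and without a role for each. Cuffdiff is named in the deposited table's own name. The authors deposited 1 table of FPKM (fragments per kilobase of transcript, scaled to the sequenced fragments of the library) for 14622 loci, with a lower and an upper confidence limit for each FPKM value. The genome build, the annotation, the scaling between libraries and the kind of confidence limit are not given in the sources used here. Positions are printed on the scaffolds as the table lists them, and whether starts are counted from 0 or 1 is also not given. Per the file headers, 5 further columns hold ratios of the FPKM values made without a pseudocount, which is the other unit in the deposited table. These ratio columns were checked against the FPKM columns and not used for the comparisons.

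The table pairs its loci with no gene names. Its identifiers were compared with a reference list of 18210 genes of the assembly ASM3026992v2, and 0 matched. The 29 gene lists fixed before the data were examined, including those for ecdysteroid synthesis, for ecdysone-responsive genes and for markers of other tissues, could therefore not be used. Loci were instead named by a rule fixed at the same time for this case: for each comparison, at most 2 identifiers with the largest and 2 with the smallest log2 ratio among the 6553 loci with a mean of at least 5 FPKM. Because several of these rest on few fragments, further loci are described by scaffold position. They were chosen after their values were seen, as the loci with the largest ratios among those with the authors' intervals apart, at least 20 implied fragments in the compared libraries and FPKM above 0 in both.

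Ratios were computed as log2 of (FPKM + 1), which understates the change of low loci, and folds given beside them are plain ratios of FPKM. The comparisons cover 8547 loci with a mean of at least 1 FPKM over the 4 libraries. A locus was called higher or lower when its log2 ratio was at least 1 in size, which is a 2-fold difference of (FPKM + 1). With 1 library per group there was no test and no p-value, and genes or loci were not treated as replicates. The 5 comparisons were PTTH against control at 1 h, PTTH against control at 3 h, control 3 h against control 1 h, PTTH 3 h against PTTH 1 h, and the difference of the PTTH ratios between the times.

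Depth was read from the confidence limits. If the distance from an FPKM value to its upper limit is 2 Poisson standard deviations, it gives the number of fragments behind the value, called implied fragments here. Among low values, 82.7% in control 1 h, 88.5% in PTTH 1 h, 88.1% in control 3 h and 86.8% in PTTH 3 h came out as multiples of 0.5 within 0.02, as fragments shared between positions would give. Standard errors of log2 ratios come from these implied fragments. They and the authors' limits cover counting error only, not variation between preparations or animals. Libraries with counting error alone were simulated 100 times at the implied depth, with the compared groups set equal.

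Neighbouring loci are consecutive tested loci on a scaffold, and called loci were shuffled over all tested loci 10000 times, or 1000 times for runs of at least 3 loci. A 95% interval of the correlation across loci was drawn by resampling whole scaffolds 1000 times. The calling step was tested on simulated data with 50 changed loci per fold and direction among 8547, all drawn from loci with a mean of at least 5 FPKM. A true 3-fold difference was called in 100% of loci in either direction at 1 h, and in 98% (higher) and 94% (lower) at 3 h. A true 1.5-fold difference, below the threshold, was called in at most 2%. Tested loci under 5 FPKM, whose ratios the added 1 FPKM shrinks more, were not covered. Computations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. The alternatives tried were pseudocounts of 0.1 and 5 FPKM, no filter and a filter at 5 FPKM, centring on the median, upper-quartile scaling, rescaling to a fixed total per library, thresholds of 1.5-fold and 4-fold, the authors' intervals, a minimum of implied fragments, and leaving out loci listed at 0.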

Results

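The prothoracic gland of insect larvae makes ecdysteroids, the steroids that drive moulting and metamorphosis, and PTTH is the brain peptide that stimulates it. Gene expression was measured by mRNA sequencing in glands of the silkworm Bombyx mori at day 4 of the fifth instar, held in Grace's medium for 1 or 3 h with or without the hormone. Each of the 4 groups was 1 library of pooled RNA, so there were no replicates and differences are given with the authors' confidence limits. The limits imply 8135000 fragments over all loci in control 1 h, 8359000 in PTTH 1 h, 9117000 in control 3 h and 10290000 in PTTH 3 h. In tested loci the median was 248 implied fragments in control 1 h, 255 in PTTH 1 h, 268 in control 3 h and 257 in PTTH 3 h. Of the 14622 loci, 8512 reached 1 FPKM in control 1 h, 8395 in PTTH 1 h, 8598 in control 3 h and 8490 in PTTH 3 h. The 100 most abundant loci of each library held 53.4% of all FPKM in control 1 h, 53.6% in PTTH 1 h, 55.2% in control 3 h and 54.9% in PTTH 3 h. Among the 100 loci with the highest mean FPKM over the 4 libraries, 0 were higher and 1 lower with PTTH by at least 2-fold at 1 h. At 3 h 2 were higher and 0 lower, 1 of the 2 being XLOC_003452 through a value listed at 0 in control 3 h.

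Which loci respond within 1 h of hormone was asked by comparing the 1 h libraries. A small set was higher with PTTH, including a locus at nscaf2943 3603651 to 3608517, a short locus at nscaf2855 6954250 to 6954626 and a low one at nscaf2930 1477270 to 1477996. Each of these was higher with the hormone at 3 h too. The lower loci included 1 at nscaf2575 4345299 to 4350998. Of 8547 tested loci, 84 were at least 2-fold higher and 82 lower, where counting error alone gave a mean of 60.8 higher and 56.2 lower and at most 140 in total. With the further demand that the authors' intervals lie apart, 40 were higher and 20 lower, against a mean of 7.71 and at most 14 from counting error alone. The balance depended on the size demanded. Intervals lay apart at any size for 284 higher and 878 lower loci, and at 1.5-fold 168 were higher and 236 lower. At 4-fold with intervals apart, 8 were higher and 9 lower. The median log2 ratio was -0.07, and after centring on it 89 loci were at least 2-fold higher and 71 lower.

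The locus at nscaf2943 3603651 to 3608517 stood at 95.2 FPKM (limits 90.6 to 99.7) in control 1 h and 1141 FPKM in PTTH 1 h, which is 12.0-fold higher. Its log2 ratio was 3.57 ± 0.04 (counting SE). The short locus at nscaf2855 6954250 to 6954626 had 61.2 FPKM (49.2 to 73.2) without and 730 FPKM (690 to 769) with PTTH, an 11.9-fold difference. At nscaf2930 1477270 to 1477996 the values were 0.760 FPKM (0.254 to 1.27) and 16.8 FPKM (14.5 to 19.0), with a log2 ratio of 3.34 ± 0.23 that rests on 9.02 implied fragments in the control. The locus at nscaf2902 9324199 to 9324679 was 5.33-fold higher, at 113 against 21.2 FPKM. Another at nscaf2937 997249 to 997759 was 5.01-fold higher, at 28.8 against 5.76 FPKM. By the fixed rule the loci named as higher are XLOC_009641 and XLOC_003827. XLOC_009641, at nscaf2964 454368 to 456443, had 64.0 FPKM (54.4 to 73.6) in PTTH 1 h, 0.193 FPKM in control 1 h and was listed at 0 in both 3 h libraries. XLOC_003827, at nscaf2686 462549 to 462699, had 22.8 FPKM in PTTH 1 h from 2.0 implied fragments, with limits of 0 to 55.1, and was listed at 0 in control 1 h.

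On the lower side at 1 h, XLOC_002860 at nscaf2575 4345299 to 4350998 had 16.7 FPKM (14.4 to 19.1) in control 1 h and 0.628 FPKM (0.197 to 1.06) in PTTH 1 h. That is 26.7-fold lower, with a log2 ratio of -3.45 ± 0.21. The difference was smaller at 3 h, when the control stood at 5.01 FPKM and the PTTH library at 3.30 FPKM. The intervals overlapped then, and the log2 ratio was -0.48 ± 0.22. The other identifier named by rule, XLOC_013650, had 11.7 FPKM from 1.5 implied fragments in control 1 h and was listed at 0 in PTTH 1 h, with overlapping intervals. A locus at nscaf2865 826992 to 828006 was 5.97-fold lower at 1 h, at 9.47 against 56.5 FPKM, and at 17.1 against 30.8 FPKM at 3 h. An abundant locus at nscaf2886 229940 to 233028 was 2.65-fold lower at 1 h, at 303 against 803 FPKM. At nscaf2930 a pair of nearby loci was lower together, 4729290 to 4734037 at 5.57 against 12.6 FPKM and 4749872 to 4754183 at 4.85 against 13.8 FPKM.

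The 3 h libraries answer the same question after longer exposure. Several loci that were low without hormone stood well above that level with it, led by 1 at nscaf2888 4905668 to 4917235. The early loci at nscaf2943, nscaf2855 and nscaf2930 had larger ratios than at 1 h. At nscaf2855 the log2 ratios, 3.91 ± 0.14 at 3 h and 3.56 ± 0.14 at 1 h, were close for their counting error. The lower loci included the abundant 1 at nscaf2886 229940 to 233028 and 1 at nscaf2204 1401844 to 1411620, both of which were higher at 3 h than at 1 h in the controls. Of 8547 loci, 243 were at least 2-fold higher and 294 lower, where counting error alone gave means of 54.7 and 52.6 and at most 128 in total. The median log2 ratio was -0.19, and after centring on it 354 loci were higher and 157 lower; with upper-quartile scaling the split was 297 higher and 200 lower. With the authors' intervals apart, 205 were higher and 235 lower, and at 4-fold or more 62 were higher and 9 lower. Smaller differences leaned the other way as deposited: 589 were higher and 1437 lower at 1.5-fold, and intervals lay apart at any size for 1118 higher and 2942 lower. At 2-fold, a pseudocount of 0.1 FPKM, which enlarges the ratios of low loci, gave 303 higher and 503 lower.

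XLOC_007718, the locus at nscaf2888 4905668 to 4917235, had 0.228 FPKM (0.0798 to 0.376) in control 3 h and 22.8 FPKM (21.3 to 24.2) in PTTH 3 h. The log2 ratio was 4.28 ± 0.10 at 3 h and 1.34 ± 0.14 at 1 h, when the PTTH library stood at 2.39 FPKM and the control at 0.339 FPKM. The control 3 h value rests on 9.48 implied fragments, and the added 1 FPKM keeps the SE small. With a pseudocount of 0.1 FPKM the 3 h ratio was 6.125, and with one of 5 FPKM it was 2.41. The locus at nscaf2930 1477270 to 1477996 reached 32.6 FPKM (29.5 to 35.7) against 1.00 FPKM (0.436 to 1.57), which is 32.5-fold. At nscaf2943 3603651 to 3608517 the values were 1382 and 81.8 FPKM, 16.9-fold apart, and at nscaf2855 6954250 to 6954626 they were 816 and 53.4 FPKM, 15.3-fold apart. A long locus at nscaf1071 74256 to 87000 was 15.1-fold higher, at 33.6 FPKM (31.8 to 35.5) against 2.22 FPKM (1.74 to 2.70), having been 3.89-fold higher at 1 h. The locus at nscaf1681 2093311 to 2096370 was 10.6-fold higher, at 565 against 53.3 FPKM, and 2.23-fold higher at 1 h. XLOC_003452, at nscaf2674 615917 to 617309, is the other identifier named by rule, because it was listed at 0 in control 3 h against 16308 FPKM in PTTH 3 h. It had 14247 FPKM in control 1 h and 13889 FPKM in PTTH 1 h, and no fold is given.

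XLOC_001851, the locus at nscaf2204 1401844 to 1411620, was 9.77-fold lower at 3 h, with 58.7 FPKM (55.6 to 61.9) in the control and 6.01 FPKM (5.06 to 6.97) with PTTH. Its log2 ratio was -3.09 ± 0.11 at 3 h and -0.78 ± 0.10 at 1 h. The locus at nscaf2886 229940 to 233028 was 8.35-fold lower, at 2524 FPKM in the control against limits of 285 to 320 FPKM with PTTH. The one at nscaf2844 34282 to 41273 was 7.79-fold lower, at 2.49 against 19.4 FPKM. Loci at nscaf2859 19877 to 25368 and nscaf2986 3882476 to 3890786 were 5.86-fold and 5.36-fold lower. At these loci PTTH 3 h lay near PTTH 1 h, at 10.3 against 10.7 FPKM and 2.96 against 2.88 FPKM. Control 3 h stood above control 1 h, at 60.4 against 14.9 FPKM and 15.8 against 3.20 FPKM. The other identifier named by rule, XLOC_009587, was listed at 0 in PTTH 3 h and had 11.6 FPKM from 2.5 implied fragments in control 3 h, with overlapping intervals.

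**Figure D1:**
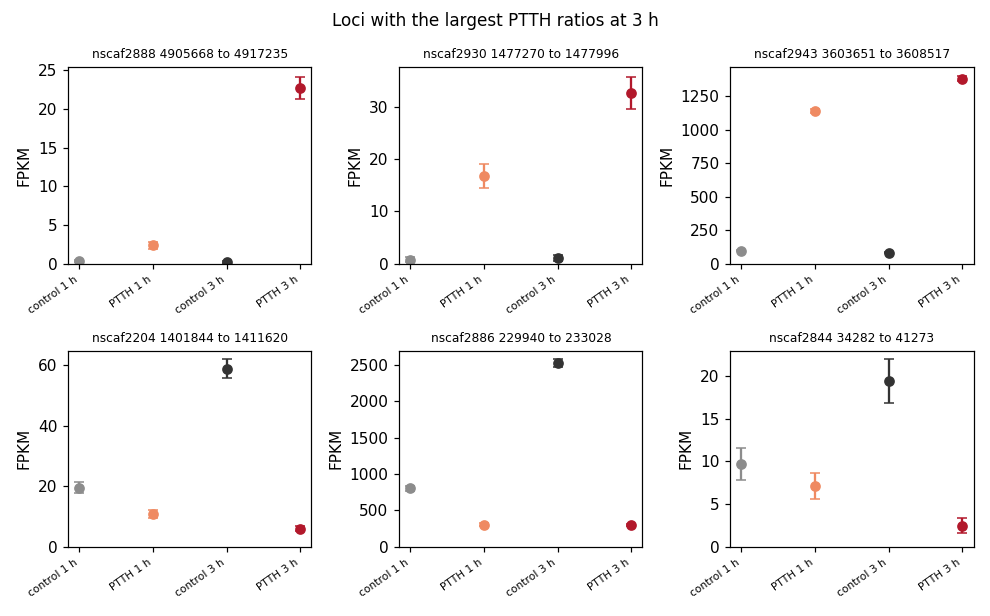
FPKM in each of the 4 libraries for 6 loci with large PTTH ratios at 3 h, with bars for the authors' confidence limits (1 library per point). The upper 3 loci were higher with PTTH at both times and the lower 3 had their highest value in control 3 h.

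How the early and the later responses relate was read from loci measured at both times. The loci raised at 1 h mostly had the same or a larger difference at 3 h, as at nscaf2943 3603651 to 3608517, while most loci that differed at 3 h had been near the control at 1 h. Of the 40 loci higher at 1 h with intervals apart, 34 were at least 2-fold higher at 3 h too, and 2 were at or below the control. A larger ratio at 3 h, by any amount and without regard to counting error, was seen in 28. Of the 20 lower at 1 h with intervals apart, 5 were at least 2-fold lower at 3 h. Of the 205 higher at 3 h with intervals apart, 139 had been within 1.5-fold of the control at 1 h, and of the 235 lower ones 215 had been. Without the demand on intervals, 38 loci were higher at both times, where independent lists of 84 and 243 would share 2.39 and counting error alone gave a mean of 9.45 and at most 18. Likewise 17 were lower at both times, against 2.82 for independent lists, a counting-only mean of 8.35 and at most 21, which covers the observed number. With intervals apart at each time, 33 were higher at both, against at most 1 from counting error alone, and 4 were lower at both, also against at most 1. Across the 8547 loci, which are not independent replicates, the ratios at 1 h and 3 h had Pearson's r of 0.333 (95% interval 0.276 to 0.390 over scaffolds) and Spearman's rho of 0.387.

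**Figure D2:**
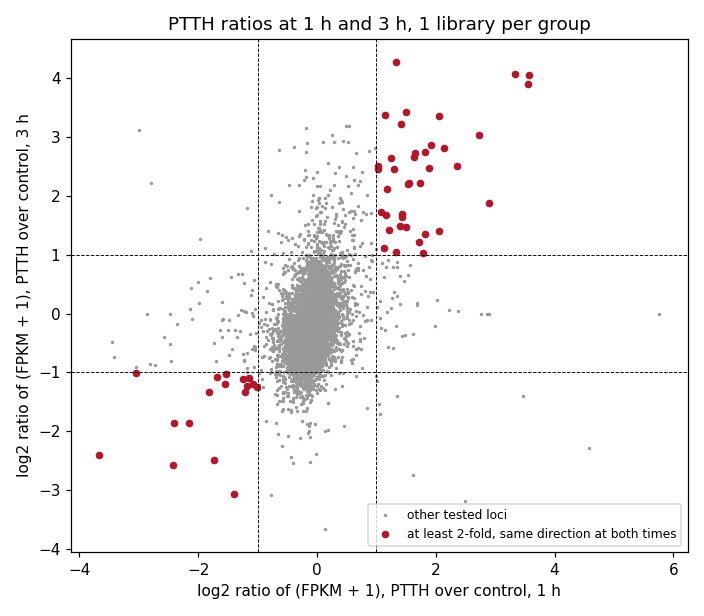
Log2 ratio of (FPKM + 1), PTTH over control, at 1 h (horizontal) and 3 h (vertical) for the 8547 tested loci except XLOC_003452, with 1 library per group. That locus, with a log2 ratio of 13.99 at 3 h, is not drawn. Red points are the 38 loci at least 2-fold higher and the 17 at least 2-fold lower at both times, and dashed lines mark 2-fold.

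The difference between the times, taken as the log2 ratio at 3 h minus that at 1 h, was at least 1 in size for 470 loci, 271 positive and 199 negative. Centred on its median of -0.11, it was positive for 332 and negative for 135, while at 1.5-fold as deposited 658 were positive and 910 negative. Counting error alone gave means of 108 positive and 108 negative, with at most 243 in total. By the fixed rule the loci with the most positive difference are XLOC_003452 at 14.03, through its 0 in control 3 h, and XLOC_001923 at 6.12. The most negative are XLOC_003827 at -6.86 and XLOC_009641 at -5.77. Loci with many fragments in this class include nscaf2888 7359787 to 7380263, which had overlapping intervals at 1 h and was 7.04-fold higher at 3 h, at 119 FPKM against 17.0 FPKM (15.6 to 18.3). Another was nscaf3022 201589 to 211571, which was 8.80-fold higher at 3 h, at 32.4 against 3.69 FPKM, and had overlapping intervals at 1 h.

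What changes in cultured glands without hormone was asked by comparing the control libraries. Gland pairs were split between medium with and without hormone, so the libraries of the times come from different pairs. A difference between the pools of larvae cannot be told from a change over time. A locus at nscaf1690 3189321 to 3196609 and a pair at nscaf2930 were higher after 3 h, and nscaf3075 951708 to 952998 was lower. Of 8547 loci, 202 were at least 2-fold higher at 3 h and 106 lower, where counting error alone gave at most 145 in total. Rescaled to a fixed total per library, 172 were higher and 182 lower, so the balance between the directions depends on the scaling. With intervals apart, 149 were higher and 61 lower. Of the 106 lower loci, 28 were higher with PTTH at 3 h, but both calls use the control 3 h library, and counting error alone gave a mean of 27.2. Of the 202 higher loci, 35 were lower with PTTH at 3 h, against a mean of 19.1 and at most 29 from counting error alone.

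XLOC_000663, at nscaf1690 3189321 to 3196609, was 7.02-fold higher in control 3 h, at 47.3 FPKM (44.9 to 49.7) against 6.74 FPKM (5.80 to 7.67), with a log2 ratio of 2.64 ± 0.10. PTTH libraries had more of it at both times, 25.8 FPKM at 1 h and 98.1 FPKM at 3 h. The pair at nscaf2930 was 4.94-fold higher at 4729290 to 4734037 and 3.96-fold higher at 4749872 to 4754183, and with PTTH 7.48-fold and 8.49-fold. The locus at nscaf2795 1615443 to 1617479 was 6.78-fold higher in the controls and 5.20-fold higher with PTTH. Of the lower loci, nscaf3075 951708 to 952998 went from 193 FPKM (186 to 200) to 59.6 FPKM (56.1 to 63.1) without hormone, while the PTTH libraries had 382 FPKM at 1 h and 423 FPKM at 3 h. The locus at nscaf2822 169275 to 169806 was 3.65-fold lower without hormone, at 4.51 against 16.5 FPKM, with 26.6 and 35.7 FPKM in the PTTH libraries. At nscaf2803 14721 to 15288 both kinds of library were lower at 3 h, by 3.37-fold without and 2.08-fold with PTTH. The remaining identifiers named by rule are XLOC_014284, at 12.9 against 1.22 FPKM with overlapping intervals, XLOC_003452, listed at 0 in control 3 h, and XLOC_000831, listed at 0 in control 3 h against 16.5 FPKM from 2.5 implied fragments.

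The corresponding comparison of the PTTH libraries asked the same under hormone, and different pools of larvae limit it in the same way. A locus at nscaf2953 445421 to 446159, a pair at nscaf2887 and the long locus at nscaf2888 7359787 to 7380263 were higher at 3 h, and a locus at nscaf2887 472569 to 473901 was lower. Of 8547 loci, 359 were at least 2-fold higher at 3 h and 148 lower, against at most 128 in total from counting error alone, and with a fixed total per library 331 were higher and 239 lower. With intervals apart, 297 were higher and 107 lower. At 1.5-fold the numbers were close, 796 higher and 778 lower, and intervals lay apart at any size for 1693 higher and 1756 lower. In both kinds of library 83 loci were higher at 3 h, where independent lists of 202 and 359 would share 8.48 and counting error alone gave at most 18. In both, 27 were lower, against 1.84 for independent lists and at most 21 from counting error alone. Control and PTTH glands of a time came from the same pairs, so larval pools that differ would add to both overlaps. Neither independent lists nor counting error covers that.

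XLOC_009484, at nscaf2953 445421 to 446159, was 72.2-fold higher at 3 h, at 38.9 FPKM (35.5 to 42.3) against 0.539 FPKM (0.131 to 0.947). In the controls it went from 0.250 FPKM, from 3.0 implied fragments, to 6.59 FPKM (5.14 to 8.03). The loci at nscaf2887 1482865 to 1484888 and 1527341 to 1529161 were 29.7-fold and 27.6-fold higher at 3 h with PTTH, at 16.9 and 19.7 FPKM, from only 4.5 and 5.01 implied fragments in PTTH 1 h. In control 3 h they stood at 1.62 FPKM (0.722 to 2.52) and 1.76 FPKM (0.745 to 2.78). XLOC_001923, at nscaf2204 849306 to 849543, had 48.9 FPKM (20.6 to 77.1) from 12.0 implied fragments and was listed at 0 in PTTH 1 h. On the lower side the identifiers by rule are XLOC_009641 and XLOC_003827, both listed at 0 in PTTH 3 h. The locus at nscaf2887 472569 to 473901 went from 171 FPKM (166 to 176) to 32.6 FPKM (30.4 to 34.7), 5.24-fold lower, and was 2.44-fold lower in the controls. On the same scaffold, 534297 to 568087 and 579306 to 584977 were 3.56-fold and 3.59-fold lower with PTTH. At nscaf2902 5081951 to 5083086 the 3 h value was 3.79-fold lower with PTTH and 2.95-fold lower without, and at 3 h the intervals of the PTTH and control libraries overlapped.

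Called loci often lay beside each other on a scaffold, both with PTTH at 3 h and, for the higher loci, over time in the controls, which was examined after the values were seen. At nscaf2888 7332539 to 7389526, 4 neighbouring loci in 57.0 kb were 4.19-fold, 7.97-fold, 7.04-fold and 9.65-fold higher with PTTH at 3 h. Their log2 ratios were 2.02, 2.91, 2.74 and 1.73 at 3 h, and 0.84, 0.11, -0.19 and 0.07 at 1 h. The last of them was low, at 3.53 FPKM with PTTH against 0.366 FPKM without at 3 h. At nscaf2838 156546 to 185118, 3 loci were 9.54-fold, 6.12-fold and 6.56-fold higher at 3 h, with log2 ratios of 1.41, 1.02 and 1.64 at 1 h. At nscaf3066 1923972 to 2017844, 3 loci in 93.9 kb were 8.63-fold, 6.20-fold and 6.15-fold higher, at nscaf2674 5596413 to 5640488 3 loci were 4.98-fold, 4.48-fold and 4.68-fold higher, and at nscaf1898 1728341 to 1760048 4 loci were 2.98-fold to 5.07-fold higher. The run at nscaf2852 1791482 to 1853050 had 3 loci at 3.86-fold, 2.95-fold and 3.56-fold. Runs of lower loci included 4 at nscaf3058 4006228 to 4130105, with log2 ratios of -1.39, -1.30, -1.50 and -1.34, and 4 at nscaf2529 4343578 to 4391889, of which 4365496 to 4365745 has overlapping intervals and 3.99 implied fragments in the 3 h libraries. There the locus 4391316 to 4391889 had 114 FPKM with PTTH against 333 FPKM without. In all, 8 runs of at least 3 neighbouring higher loci held 26 loci, against a mean of 0.175 runs and at most 2 in 1000 shuffles. One of the 8, at nscaf2828 2510135 to 2549076, has overlapping intervals at 2 of its 3 loci. For lower loci there were 4 runs with 14 loci, against a mean of 0.337 and at most 4, so that count lies within the range of the shuffles. Pairs of neighbours both higher numbered 38, against a mean of 6.56 and at most 19 in 10000 shuffles, and pairs both lower numbered 34, against 9.67 and at most 23. Without hormone, loci higher in control 3 h than in control 1 h formed 31 neighbouring pairs, against a mean of 4.57 and at most 15, and 5 runs with 18 loci, against at most 2 in the shuffles. The lower ones formed 5 pairs, against at most 8, and 0 runs. The longest of the higher runs, 6 loci at nscaf1071 346991 to 409845, rests on few fragments in control 1 h, where 2 of the 6 were listed at 0. Another run, 3 loci at nscaf2795 1656057 to 1682261, had 15.4, 4.04 and 17.5 FPKM in control 1 h and 62.6, 18.2 and 72.0 FPKM in control 3 h.

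**Figure D3:**
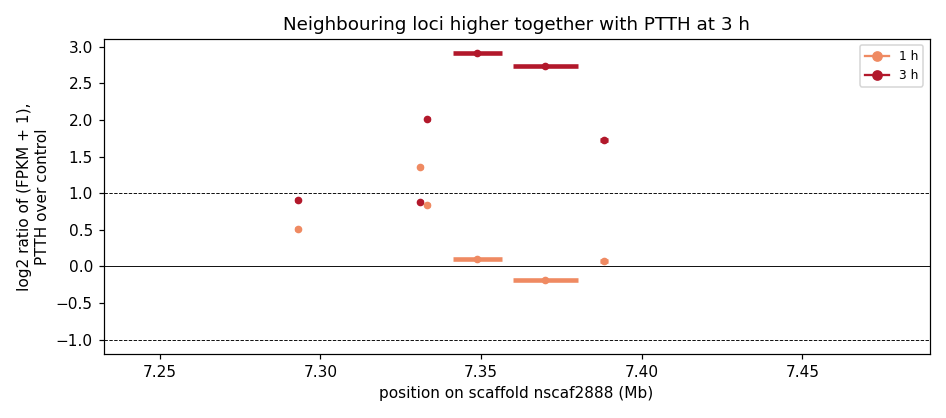
Log2 ratio of (FPKM + 1), PTTH over control, for tested loci on scaffold nscaf2888, against position in Mb, at 1 h (orange) and 3 h (dark red); horizontal bars span each locus. The run from 7332539 to 7389526 holds 4 loci above 2-fold at 3 h.

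**Figure D4:**
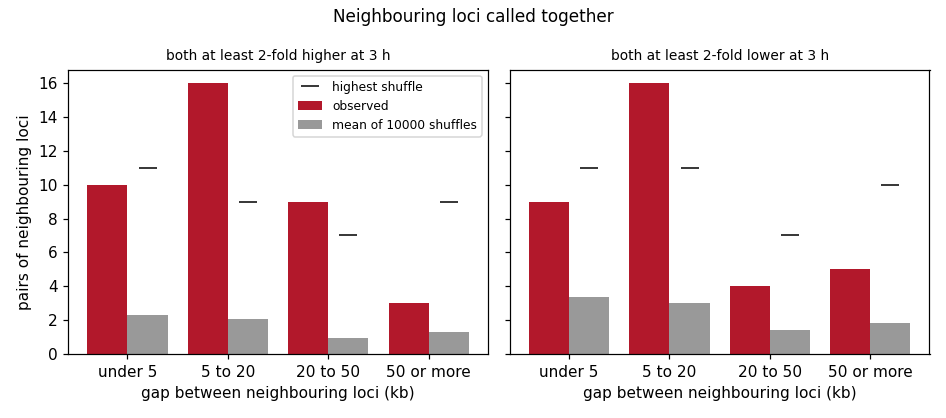
Number of pairs of neighbouring loci both at least 2-fold higher (left) or lower (right) with PTTH at 3 h, by the gap between them in kb, beside the mean and the highest of 10000 shuffles. Higher pairs 5 to 20 kb apart numbered 16, against a mean of 2.06 and a highest of 9.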

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

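The test below was chosen after the result was seen. XLOC_001923, at nscaf2204 849306 to 849543, and XLOC_003827, at nscaf2686 462549 to 462699, stood out because the PTTH and control libraries differed in opposite directions at the 2 times. The log2 ratio at 3 h minus that at 1 h was 6.12 for XLOC_001923, which was listed at 0 in PTTH 1 h and had a log2 ratio of 3.12 at 3 h. For XLOC_003827 it was -6.86, from 4.57 at 1 h to -2.28 at 3 h. With 1 library per group the difference between the times was not tested.

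In all, 13 loci were at least 2-fold apart in opposite directions, 8 higher and then lower, and 5 lower and then higher. They held a median of 3.52 implied fragments over the 4 libraries, and a range of 2.01 to 35.5. Libraries simulated with counting error alone gave a mean of 16.7 loci with opposite ratios, and a range of 8 to 24. Counting error at few fragments may therefore account for the 13. None had the authors' intervals apart at both times, which decides little at such depth. A hormone effect that turns over between 1 h and 3 h stays open and untested for the 2 loci with intervals apart at either time. These are XLOC_001923, with 15.0 implied fragments over the 4 libraries, and XLOC_005715, with 23.5, which was named after its values were seen.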

How the results depend on the processing

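The alternatives were fixed before the data were examined, except the minimum of implied fragments and leaving out loci listed at 0, which were chosen after seeing the data. No named locus changed direction, which says little: a pseudocount cannot turn the sign of a ratio, and these loci were named for large ratios. Log2 ratios were recomputed under 5 alternatives for 62 pairings of a named locus and a comparison. Of these ratios, 242 stayed within the range that the authors' limits span and 68 moved beyond it. That range is wide for loci on few fragments, so staying within it says little for those. Of those 68, a pseudocount of 5 FPKM gave 29 and one of 0.1 FPKM gave 23, while centring gave 7, rescaling to a fixed total 5 and upper-quartile scaling 4.

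Counts of loci at least 2-fold apart moved most with the threshold, by its construction. At 1.5-fold, the count became 404 at 1 h, 2026 at 3 h, 1299 for the controls over time, 1574 for the PTTH libraries over time and 1568 for the difference of ratios. At 4-fold these were 40, 87, 35, 83 and 82. Loci higher with PTTH at both times numbered 93 at 1.5-fold and 7 at 4-fold, and those lower at both times 101 and 2. A pseudocount of 5 FPKM, which shrinks the ratios of low loci, gave 66 at 1 h, 253 at 3 h, 139 for the controls, 257 for PTTH over time and 213 for the difference. A pseudocount of 0.1 FPKM gave 806 at 3 h and 492 for the controls.

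The 1 h count of 166 depended on low loci: it was 86 with a mean of at least 5 FPKM, 60 with the authors' intervals apart and 64 with at least 10 implied fragments per library on average. The 17 loci lower at both times became 36 with a pseudocount of 0.1 FPKM and 2 with one of 5 FPKM. They were 4 with a mean of at least 5 FPKM, 4 with the authors' intervals apart, 10 after centring and 9 without loci listed at 0. The correlation of the ratios at 1 h and 3 h, 0.333 as reported, was 0.222 with a pseudocount of 0.1 FPKM and 0.428 with one of 5 FPKM. It was 0.419 with a mean of at least 5 FPKM and 0.417 without loci listed at 0. Beyond what the filters remove, the cause was not tested. The 3 h count kept within 1.5 times of 537 under the filters, the scalings and the authors' intervals, from 424 to 579.

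Individual gland pairs cannot be followed, because each group is 1 pooled library. The PTTH ratio at each time compares pools of paired glands, and no test joining the times was run. Keeping loci with a poor status could not be run, since the table has no status column, nor could the authors' intervals be applied to the difference of ratios. The alternatives for the gene lists could not be run without gene names. Depth limits low loci: under 20 implied fragments lay behind 44 of the 84 higher and 58 of the 82 lower loci at 1 h, and behind 39 of 243 and 53 of 294 at 3 h.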

Other observations

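The tests of neighbouring loci and of the median ratio were chosen after the results were seen. Neighbouring loci were higher together at 3 h, as in the run at nscaf2888 7332539 to 7389526. They were so over time in the controls too, in 31 pairs against at most 15 in the shuffles, so clustering also arose without the hormone. The control runs lay on other scaffolds than the runs higher with PTTH, and whether the clusters share a cause was not tested. Pieces of one transcript split over neighbouring loci would share their plain PTTH fold. The 1 FPKM added to each value shrinks log2 ratios of low loci, however. In the nscaf2888 run, neighbours 7.04-fold and 9.65-fold higher had log2 ratios of 2.74 and 1.73. Of 35 pairs higher at 3 h with fragments enough for a value, 28 had ratios within 3 counting SEs at each time with a value. The other 7 differed by more, which is 20% against 43.6% of 10000 random pairs of higher loci. Split transcripts may account for part of the clustering, but the test does not decide it. Pieces at unlike levels can differ, and neighbours that change together for another reason can be alike. Earlier forms of the test pointed the other way, with 12 pairs at least 20 kb apart against at most 10 in the shuffles and 14 of 38 pairs over 4-fold apart in level, but were replaced because the spacing and levels of such pieces were not measured. Reads shared between near-identical neighbours and a joint change of a chromosome region stay open too, since neither sequences nor gene names were analysed here.

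The median PTTH ratio at 3 h lay below 0, at -0.19. With 1 FPKM added to every value, one scale factor between the libraries would shift abundant loci at least as far as low ones. The most abundant of 8 bins of mean FPKM instead had a median of -0.08, which is 0.188 above the -0.27 of loci at 5.42 to 9.31 FPKM. That argues against a scale factor as the whole cause. The shift also differed with implied length, from a weakest median of -0.12 ± 0.01 (bootstrap SE) to -0.23 ± 0.01 in the longest bin, and no length bin lay at 0. With a single library per group, these SEs cover no variation between preparations or animals. A length bias may therefore account for part of the shift or, with an offset common to all lengths, for more of it. At 1 h the median was also weakest in the most abundant bin, at -0.02, against -0.12 at 2.76 to 5.42 FPKM. Spearman's rho of the ratio with implied length was -0.07 for PTTH at 3 h. For control 3 h against control 1 h it was 0.12, so a trend with length also arose between libraries without hormone. A scale factor for part of the shift and a broad hormone effect on loci of middle abundance stay open too, and a single library per group does not separate them.

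XLOC_003452, at nscaf2674 615917 to 617309, was listed at 0 in control 3 h and at 13889 FPKM or more in the other libraries. Among the 3255 loci with at least 20 FPKM in at least 3 libraries, 1 was listed at 0 in exactly 1 library. Whether its 0 is a failed estimate or a loss of the transcript was not tested. XLOC_009641, at nscaf2964 454368 to 456443, was the reverse case, with 177 implied fragments in PTTH 1 h and under 1 in every other library.

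The deposited ratio columns matched the FPKM columns in the 4 simple ratios. The column whose header names a ratio of the 1 h and the 3 h ratios equalled PTTH 3 h over control 1 h in all 10643 numeric cells, within a relative 1e-06.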
